A study of Xenopus tropicalis x Xenopus laevis and Xenopus tropicalis with 6 samples.

How the data were processed

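Whole embryos were collected 7 hours after fertilization from 2 groups, hybrids of *X. tropicalis* eggs and *X. laevis* sperm and *X. tropicalis* embryos, with 3 libraries per group. Per the labels' protocols, embryos were homogenized in TRIzol, RNA was cleaned on RNeasy columns with DNA digestion, polyA RNA was selected with Dynabeads, and libraries were prepared on an Apollo324 robot with PrepX kits and PCR amplification. Per the submitters' processing notes, BWA 0.7.10 was among the tools used. The counting program, the transcript models, the genome builds and any filter are not given in the sources used here, and neither is whether counting used strand. Reads shared by the L and S copies, or by both species, may have been counted on either.

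The authors deposited raw counts per feature, without normalization, in a table of 45244 features, and a second table of counts summed to human gene names. The sums of the feature table equalled the second table for 14145 of its 14146 names, so the second table is a sum over both species. Of the names, 10985 had features of both species, 1658 only of *X. laevis* and 1503 only of *X. tropicalis*. Another 7597 features carried no human name. Human names can join different genes: the features behind *PDK2* are named pdk4, those behind *RPS20* are named rbm6, most counts behind *SNAI2* lie on snai1 features, and nearly all counts behind *S1PR1* lie on s1pr5. The species and chromosome of each feature were read from its name, and no genome sequence was used, so no coordinates are given. The mitochondrially encoded names were counted on few features, of which that of *MT-CO3* is placed on a nuclear chromosome in the table.

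Groups were taken from the labels. The replicate numbers are not shared between groups, so no pairing was fitted. Replicates of a group differed by far more than counting noise (chi-square per degree of freedom from 114 to 195 over the genes of each pair), and none was treated as a repeat deposit. Total counts ranged from 71435751 to 100025277 per library. The p-values measure the spread between these libraries, which the series text describes as biological replicates. Where a group had no count, a floor of 3 counts over its libraries was used for a lower bound of the fold, and count ratios against 1 to 3 counts carry 95% exact binomial intervals. PCR copies are not independent molecules, so intervals and floors cover counting error only. Shares of features carry exact binomial (Clopper-Pearson) 95% intervals.

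Counts were tested with the edgeR quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with TMM factors, the edgeR filter for low counts and Benjamini-Hochberg adjustment at 0.05, separately for human-named genes and for *X. tropicalis* features. Standard errors are the log2 fold change divided by the square root of F. The common biological coefficient of variation was 0.526 for human-named genes and 0.649 for *X. tropicalis* features. *X. laevis* features with at least 10 counts over the hybrid libraries were tested against the *X. tropicalis* libraries as background, with TMM factors from *X. tropicalis* features and library totals over all features (coefficient 1.29). CPM are counts scaled to the effective library size. For chromosomes, the net level is the summed hybrid CPM minus the mean *X. tropicalis* CPM, per feature, and the contrast of 3L and 4L with the other L chromosomes was tested by exact permutation over chromosome pairs. The share of *X. laevis* counts was tested by exact permutation over 20 labelings. Chromosomes are not independent samples, and that permutation describes how unusual this pair is among the L chromosomes of these libraries.

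The 21 gene lists were fixed before the data were examined, as were the tests, the rule for named genes and the alternatives, except those that the text says were chosen after seeing the data. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, and again with an estimated correlation and with fry. The called lists were p53 targets, ribosomal proteins, oxidative phosphorylation, organizer, and ventral and BMP response, and with an estimated correlation 0 of the 21 passed, with 2 at an unadjusted p under 0.05. Named genes are, for human names, the 10 largest rises and 10 largest falls among genes with adjusted p under 0.05, an average log2 CPM over 1, groups without overlap and a gene symbol, and the 4 members of each list with the smallest adjusted p (or up to 2 with the smallest p where none passed). For *X. tropicalis* features they are the 5 largest each way by the same rule. For *X. laevis* features they are the 10 with the highest hybrid level among those above background with a gene symbol. Not every gene that this rule takes is reported here. Other members are named only where the text says that they were chosen after their values were seen. The figures were drawn with matplotlib 3.10.9.

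The tests were checked on simulated counts with 200 changed genes drawn from the means, dispersions and library sizes of the data. The means were taken over the libraries of both groups, and the effective library sizes were kept, so the TMM step was not checked. In the simulation of human-named genes, tested on 12436, 86.7% of genes changed by 2 on the log2 scale and 61.8% of those changed by 1 were recovered, with 11 calls among unchanged genes. For *X. tropicalis* features (13480 tested, 2 calls among unchanged features) the shares were 84.2% and 48.8%, and for *X. laevis* features (19705 tested, 12 such calls) 52.9% and 1.04%. Of 20 random lists of 30 genes, the 1 that had been shifted was called and 0 of the rest. These genes were drawn independently, so the simulation does not check the list test for correlated members. The estimated correlation in the data was 0.37 for ribosomal proteins and 0.20 for organizer. Alternatives were DESeq2 1.42.0, RLE factors or library totals, no filter, a filter of 5 CPM in 3 libraries, a test beyond 1.5-fold, library sizes over all features, names or features of a single species, other measures of the chromosome contrast, and leaving out each library in turn.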

Results

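The series asked how gene expression differs between inviable *Xenopus* hybrid embryos and embryos of the maternal species at 7 hours after fertilization, and what happens to the paternal genome in the hybrids. Eggs of *X. tropicalis* fertilized with *X. laevis* sperm gave the hybrid libraries (replicates 40, 41 and 42), and *X. tropicalis* embryos gave the comparison libraries (replicates 37, 38 and 39). PolyA RNA of whole embryos was sequenced, with 3 libraries per group that the series describes as biological replicates. The counts summed to 76074546, 88526278 and 71435751 in the hybrid libraries and to 94373967, 90144765 and 100025277 in the *X. tropicalis* libraries. The feature table held 18062 *X. tropicalis* and 27182 *X. laevis* features. *X. laevis* is allotetraploid, so its features lie on long (L) and short (S) homeologous chromosomes. A second table summed the features of both species under 14146 human gene names.

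Paternal transcripts made up a measurable part of the hybrid messenger RNA. *X. laevis* features took 16.7% ± 1.203 of all counts (SD, n = 3) in hybrids, against a background of 5.66% ± 0.302 (SD, n = 3) in *X. tropicalis* libraries, where no *X. laevis* genome was present. The single hybrid libraries gave 15.4%, 17.3% and 17.6%, and the *X. tropicalis* libraries 5.33%, 5.92% and 5.72%. The difference of 11.1 percentage points was larger than the spread between replicates, and the 2-sided exact permutation test gave p = 0.1, the smallest value that 3 against 3 libraries allow. After leaving out the 13883 features whose background exceeded 1% of their hybrid level, the share was 8.11% ± 0.708 (SD, n = 3) in hybrids, while the share left in *X. tropicalis* is set by that selection and is not given. *X. laevis* reads assigned to *X. tropicalis* features were not measured, since no library held *X. laevis* RNA alone.

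Of 23919 *X. laevis* features with at least 10 counts over the hybrid libraries, 9669 lay above the *X. tropicalis* background (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted). Features named by a model number were left out of the following ranking. Among paternal features named by a gene symbol, those with the highest hybrid level encoded an AMP-transferring enzyme of the endoplasmic reticulum (ficd.S, 1328 CPM ± 127, SD, n = 3), the cold-inducible RNA-binding protein (cirbp.L, 837 CPM ± 110.5, and cirbp.S, 617 CPM ± 100), the chromatin protein hmgb3.L (818 CPM ± 97.7) and anp32c.S (711 CPM ± 109). They were followed by the apelin receptor aplnr.L (666 CPM ± 55.6), the splicing factors srsf2.L (548 CPM ± 47.2) and srsf5.S (430.5 CPM ± 63.0), marcksl1.S (514 CPM ± 94.5) and rasl11b.L (357 CPM ± 50.4). Their background in *X. tropicalis* libraries was 0.482 to 4.21 CPM, except for ficd.S at 104 CPM ± 7.25. Another 47 *X. laevis* features were lower in hybrids than in *X. tropicalis* libraries. With a filter of 5 CPM in 3 libraries, 4500 features were tested and 2997 lay above background.

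The paternal chromosomes did not contribute evenly. Known work on this cross reported loss of parts of *X. laevis* chromosomes 3L and 4L, and these chromosomes were compared with the other L chromosomes. Chromosome 3L gave 1.503 net CPM per feature ± 0.286 and 4L gave 1.09 ± 0.107 (SD, n = 3 hybrid libraries), where net CPM is the hybrid level minus the mean *X. tropicalis* background. The other 7 L chromosomes gave 3.87 to 5.54 and the 9 S chromosomes 3.85 to 6.57, with 3S at 3.93 ± 0.427 and 4S at 3.92 ± 0.616. On the log2 scale 3L and 4L differed from the other L chromosomes by -1.87, a 3.66-fold deficit. No other pair among the 36 possible pairs of L chromosomes gave a difference as large, so the 2-sided exact permutation test gave p = 0.0278, the smallest value it allows. The share of features above background was 17.4% on 3L and 18.1% on 4L, with exact binomial 95% intervals of 15.5 to 19.4% and 16.1 to 20.3%, against 35.0 to 38.4% on the other L chromosomes (exact permutation p = 0.0278).

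**Figure D1:**
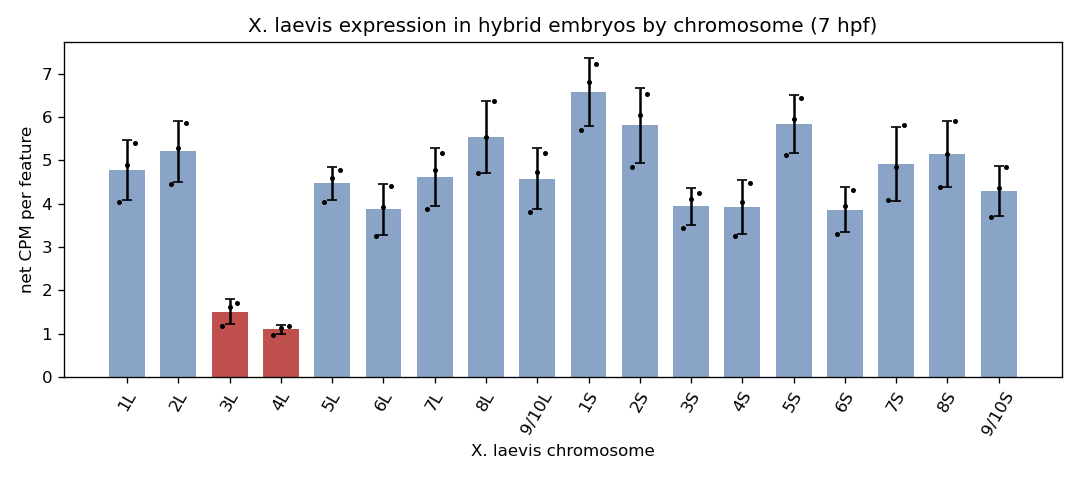
Net CPM per *X. laevis* feature in hybrid embryos (y axis) for each L and S chromosome (x axis). Bars are means of the 3 hybrid libraries, error bars are SD and points are single libraries; 3L and 4L (red) stand at 1.503 and 1.09, all other chromosomes (blue) at 3.85 or above.

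The deficit was also seen relative to the *X. tropicalis* copies of the same genes, whose counts may include RNA already in the egg. Orthologous *X. laevis* genes on 3L and 4L reached 2.21% and 1.89% of the level of their *X. tropicalis* orthologues in the same hybrid libraries, against 6.94 to 11.4% for the other L chromosomes (log2 difference -2.10, exact permutation p = 0.0278). The *X. tropicalis* orthologues themselves differed by 0.08 on the log2 scale (exact permutation p = 0.278). Without subtraction of the background the difference was -0.98 (exact permutation p = 0.0278). The features of 3L summed to 3578 CPM in *X. tropicalis* libraries and 5793 CPM in hybrids.

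Counted under human gene names, 641 of 12682 tested genes were higher in hybrids and 362 were lower, 538 and 172 of them by more than 2-fold. The C3a receptor gene *C3AR1* stood at 67.5 CPM ± 7.28 (SD, n = 3) in hybrids and 0.0896 CPM ± 0.0380 in *X. tropicalis* (log2 fold change 9.53 ± 0.33 SE, adjusted p = 6.93e-08). The carboxypeptidase gene *CPA6* and the arginase gene *ARG2* had no count in *X. tropicalis* and were at least 483-fold and 442-fold higher in hybrids, against a floor of 3 counts over the 3 libraries. With 1 or 2 counts in *X. tropicalis*, the acetylcholine receptor subunit *CHRNG* gave a count ratio of 1848 (95% counting interval 331 to 73022), the cadherin gene *CDH18* 1436 (257 to 56780), the planar polarity gene *VANGL1* 1386 (248 to 54790), *CTLA4* 1001 (277 to 8268), *GUCY1A2* 897 (248 to 7412), *SCHIP1* 872 (241 to 7209) and *SLC26A1* 795 (220 to 6571). These intervals cover counting error only. *C3AR1*, *CHRNG*, *CDH18*, *VANGL1*, *CTLA4*, *SCHIP1* and *SLC26A1* have *X. laevis* features alone in the table, so their *X. tropicalis* value is background on a paternal feature and the ratio is not a difference in expression of the gene between groups. The hybrid level of *ARG2* lay mostly on the paternal feature arg2.S (4.61 CPM), with the *X. tropicalis* feature arg2 at 0.244 CPM. Its 442-fold bound therefore rests mostly on a paternal feature. *CPA6* and *GUCY1A2* were counted mostly on *X. tropicalis* features in hybrids (cpa6 at 5.01 CPM, gucy1a2 at 5.71 CPM). How many *X. laevis* reads lay on cpa6 and gucy1a2 was not measured.

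The largest falls were in *S1PR1* (log2 fold change -6.13 ± 0.47 SE), which stood at 2.42 CPM ± 1.46 in hybrids and 168 CPM ± 20.9 in *X. tropicalis* and whose counts came almost wholly from the feature s1pr5. *SKIDA1* fell by 4.05, the serine dehydratase gene *SDS* by 3.39, the aminopeptidase gene *ANPEP* by 3.32 and the actin-binding *TAGLN2* by 3.32 on the log2 scale. The homeobox genes *IRX2* (-3.12), *HOXD1* (-2.94) and *MSX1* (-2.73), the neural zinc finger gene *MYT1* (-2.81) and *UGT3A2* (-3.11) also fell. *ANPEP*, *TAGLN2* and *UGT3A2* have no *X. laevis* feature, so paternal transcripts of them could not be counted. Their falls are of *X. tropicalis* features alone. The adjusted p of these genes ranged up to 0.0181 (*ANPEP*, edgeR), and *ANPEP* lost its call without hybrid replicate 40 or 42 or *X. tropicalis* replicate 38, with adjusted p up to 0.0729. In *X. tropicalis* libraries irx2.L took more counts than irx2 (92.3 against 59.4 CPM), so the species split of *IRX2* is uncertain.

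Paternal features carried much of the rise. Of the 641 higher genes, 509 drew more than 50% of their hybrid level from *X. laevis* features, with a median of 90.7%, against a median of 10.8% over all tested genes. Of the 362 lower genes, 50 did so, with a median of 10.6%. Among names without an *X. tropicalis* feature, 174 of 972 were higher (17.9%), and among names with features of both species 457 of 10652 (4.29%). The former are counted on *X. laevis* features in both groups, so these percentages do not compare expression of the genes. Restricted to *X. tropicalis* features, the same test called 90 names higher and 350 lower. The counts also moved with single libraries: without hybrid replicate 41 there were 344 higher and 164 lower genes, without hybrid replicate 42 there were 377 and 199, and the lower genes numbered 224 and 189 without *X. tropicalis* replicates 37 and 39.

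In the p53 and DNA damage list, 10 of 33 measured members were higher and 1 was lower, with a median log2 fold change of 0.19, or 12 and 2 adjusted over the list alone (camera adjusted p = 1.33e-09; adjusted p = 0.0732 with an estimated correlation). *MDM2*, the ubiquitin ligase that degrades p53, rose from 65.1 CPM ± 9.46 to 380 CPM ± 31.2 (SD, n = 3; log2 fold change 2.54 ± 0.14 SE, adjusted p = 1.84e-06). The cell cycle inhibitor gene *CDKN1A* rose from 5.35 CPM ± 2.05 to 127 CPM ± 2.92 (log2 fold change 4.56), the sestrin gene *SESN1* from 6.93 CPM ± 2.69 to 109 CPM ± 15.7 (3.97), and the cyclin gene *CCNG1* from 74.7 CPM ± 31.4 to 879 CPM ± 138 (3.56). The other higher members were *GADD45B*, *PLK2*, *EDA2R*, *SESN2*, *TP53INP1* and *GADD45G*, and the lower member was the checkpoint kinase gene *CHEK1* (-0.94); these are named after their values were seen. All 10 higher members kept their call with each library left out in turn, while *CHEK1* lost it without hybrid replicate 41 or 42 or *X. tropicalis* replicate 37 or 39 (adjusted p up to 0.177).

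**Figure D2:**
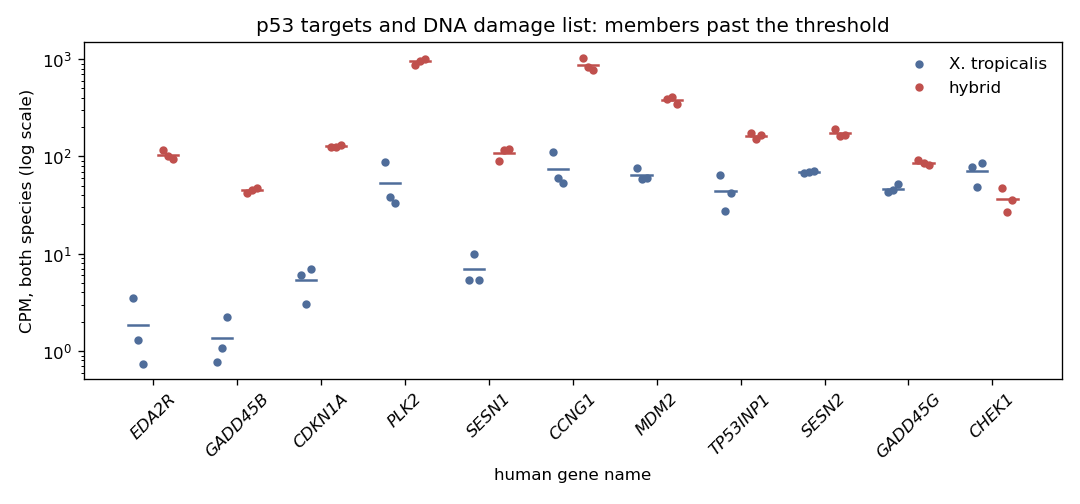
CPM summed over both species (y axis, log scale) of the 11 members of the p53 and DNA damage list that passed the test (x axis). Points are single libraries and bars are group means of 3; the 10 higher members separate fully from *X. tropicalis*, as does the lower *CHEK1* (36.6 against 70.4 CPM).

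Of the 10 higher p53 list members, 7 were called higher over *X. tropicalis* features alone, among them *MDM2* (2.38), *CDKN1A* (3.13), *CCNG1* (2.99) and *SESN1* (1.496), and the list stayed higher (camera adjusted p = 6.02e-09; adjusted p = 0.0349 with an estimated correlation). *GADD45B*, also among the 7, has an *X. tropicalis* feature alone, so both counts of it rest on the same feature. This choice of features for the lists was made after seeing the data. How many *X. laevis* reads lay on the *X. tropicalis* features of these genes was not measured.

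In the pyruvate and TCA cycle list, 1 of 33 measured members was higher and 1 lower (adjusted over the list alone also 1 and 1). The higher one carries the human name *PDK2* but was counted on pdk4 features, a kinase that inhibits pyruvate dehydrogenase; it rose from 7.67 CPM ± 0.186 to 201 CPM ± 27.0 (SD, n = 3; log2 fold change 4.71 ± 0.16 SE, adjusted p = 6.93e-08). About equal parts came from the *X. tropicalis* feature pdk4 (98.9 CPM) and from pdk4.S (101 CPM). The related kinase gene *PDK1* fell by 1.79. In glycolysis, 2 of 24 members were lower and 0 higher in the edgeR test, also adjusted over the list alone (5 lower and 3 higher at an unadjusted p under 0.05, 3 and 1 with DESeq2). They were the regulatory enzyme gene *PFKFB3* (-0.58) and the hexokinase gene *HK2* (-0.65). *PFKFB3* lost its call without hybrid replicate 41 (adjusted p = 0.0524), and *HK2* without hybrid replicate 41 or 42 or *X. tropicalis* replicate 37 or 39 (adjusted p up to 0.0978). Neither list passed (camera adjusted p = 0.511 for the pyruvate and TCA cycle list and 0.783 for glycolysis). The pyruvate and TCA cycle list passed as higher over *X. tropicalis* features alone, a choice made after seeing the data, with a median of 0.19 (camera adjusted p = 6.32e-04; adjusted p = 0.107 with an estimated correlation).

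Nuclear genes of oxidative phosphorylation were higher as a list with 1 of 73 members called higher (also 1 adjusted over the list alone) and a median log2 fold change of 0.28 (camera adjusted p = 0.0395; adjusted p = 0.668 with an estimated correlation). The called member, the cytochrome oxidase subunit gene *COX8A*, went from 0.0418 CPM ± 0.0340 to 8.30 CPM ± 1.43, of which 99.8% lay on *X. laevis* features. Its counts in *X. tropicalis* also lay on an *X. laevis* feature, so this rise is against background. The list lost its call without hybrid replicates 41 or 42 and *X. tropicalis* replicates 37 or 39, with adjusted p of 0.0754, 0.0710, 0.247 and 0.0595. Counted over *X. tropicalis* features alone, edgeR called 0 of 64 members and DESeq2 4 higher (17 higher and 0 lower at an unadjusted p under 0.05), and the list passed (camera adjusted p = 1.65e-06; adjusted p = 0.227 with an estimated correlation). Of the 4 mitochondrially encoded genes, 0 passed with edgeR over all genes and 2 were higher adjusted over the list alone (2 at an unadjusted p under 0.05, 1 with DESeq2; camera adjusted p = 0.577); *MT-CO3* stood at 1561 CPM ± 815 and 901 CPM ± 223, and *MT-ND1*, counted on a feature assigned to *X. laevis* alone, at 173 CPM ± 65.7 and 101 CPM ± 20.3. Without hybrid replicate 40 this list passed (camera adjusted p = 0.0291).

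In fatty acid oxidation, 1 of 30 members was higher (*ECI1*, 1.54). In cholesterol and lipid synthesis, 2 of 29 were higher: *LSS*, the lanosterol synthase gene (3.005, 22.1 against 2.75 CPM, 0.136% of it on *X. laevis* features), and the desaturase gene *FADS2*, with 1061 counts against 2 (ratio 622, 95% counting interval 172 to 5139), of which 94.6% in hybrids and both in *X. tropicalis* lay on the *X. laevis* feature, so the ratio is mostly against background. In pentose phosphate and nucleotide synthesis, 2 of 35 were higher (*CTPS1*, 1.09, and *NME2*, 0.67) and 2 lower (*TK1*, -0.69, and *IMPDH1*, -0.49). In amino acid and one-carbon metabolism, 3 of 35 were higher (*PSAT1*, 2.16, *ARG1*, 6.05, all of its hybrid counts on the *X. laevis* feature, and *MAT2A*, 0.57) and 1 lower, the tyrosine aminotransferase gene *TAT* (-1.23). The rise of *PSAT1* lay mostly on psat1.S (16.0 CPM in hybrids), with the *X. tropicalis* feature psat1 at 5.95 CPM in hybrids and 4.89 CPM in *X. tropicalis*. Adjusted over the list alone, the counts were 1 and 0, 2 and 0, 2 and 3, and 3 and 1 for these lists in that order. None of them passed as a list (camera adjusted p from 0.445 to 0.975). Leaving out a library in turn, *IMPDH1* lost its call in all 6 fits (adjusted p up to 0.120), *ECI1* in all but that without *X. tropicalis* replicate 38 (up to 0.157), *NME2* without hybrid replicate 41 or 42 or *X. tropicalis* replicate 37 or 39 (up to 0.145), *TK1* without hybrid replicate 42 or *X. tropicalis* replicate 39 (up to 0.0603) and *MAT2A* without hybrid replicate 41 (0.0528). Over *X. tropicalis* features alone *CTPS1* stood at -0.37 and *MAT2A* at -0.20 without passing.

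Ribosomal protein genes were higher as a list, with 6 of 76 members called higher and 0 lower in the edgeR test, or 8 and 0 adjusted over the list alone (28 and 0 at an unadjusted p under 0.05, 15 and 0 with DESeq2; median log2 fold change 0.38, camera adjusted p = 1.01e-04; adjusted p = 0.668 with an estimated correlation). *RPS13* (1.84), *RPS12* (1.66), *RPS9* (1.44) and *RPS20* (0.65) were the members with the smallest adjusted p. Over *X. tropicalis* features alone *RPS20* kept its call (0.60), and *RPS13* was at 0.07, *RPS12* at 0.90 and *RPS9* at 0.74 without passing. The higher members numbered 3 without hybrid replicate 41 or 42 or *X. tropicalis* replicate 37 or 39, and 11 without *X. tropicalis* replicate 38. *RPS20* lost its call over both species without hybrid replicate 41 or 42 or *X. tropicalis* replicate 37 or 39 (adjusted p up to 0.0976). All 3 features summed under *RPS20* are named rbm6, after an RNA-binding protein gene, so this call may not concern the ribosomal protein gene. The ribosomal list also passed over *X. tropicalis* features alone (camera adjusted p = 1.05e-05; adjusted p = 0.486 with an estimated correlation). Ribosomal protein genes have near-identical copies, so their split between species is uncertain.

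In the unfolded protein and heat shock list, 3 of 32 members were higher and 2 lower, with the same counts adjusted over the list alone (camera adjusted p = 0.975). *HERPUD1*, a degradation factor of the endoplasmic reticulum, rose from 80.2 CPM ± 16.3 to 360.3 CPM ± 71.7 (log2 fold change 2.17), with 1.87% on *X. laevis* features. The chaperone gene *HSPA5* rose by 0.69, while the stress transcription factor gene *XBP1* (-0.87) and the calnexin gene *CANX* (-0.69) fell. The rise of *HSPA5* lay mostly on hspa5.S (132 CPM in hybrids), with the *X. tropicalis* feature hspa5 at 257 CPM in hybrids and 245 CPM in *X. tropicalis*. In the apoptosis list, *BIRC2* fell (-1.42), *BIRC3* was at least 153-fold higher on an *X. laevis* feature alone, and the other 24 of 26 members did not pass (3 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.975). In DNA replication and mitosis, 3 of 57 members were higher and 3 lower, also adjusted over the list alone (camera adjusted p = 0.975). The cyclin gene *CCNE2* (0.93) and the oocyte and embryo kinase gene *WEE2* (0.84) were higher, and the cyclin gene *CCNB3* (-0.70) and the phosphatase gene *CDC25B* (-1.40) were lower. In the centromere and kinetochore list, 2 of 40 were higher and 2 lower, also adjusted over the list alone (camera adjusted p = 0.621). *CENPA*, the histone of centromeres, was higher (0.43), *PMF1* had 842 counts against 2 (ratio 493, 95% counting interval 136 to 4080) on an *X. laevis* feature alone, so its ratio is against background, and *SMC1A* (-0.62) and *CENPF* (-0.48) were lower. Over *X. tropicalis* features alone *CCNE2* was called lower (-1.65). Leaving out a library in turn, *CENPA* and *CENPF* lost their call in all fits but that without *X. tropicalis* replicate 38 (adjusted p up to 0.127 and 0.195), *SMC1A* without any hybrid replicate or *X. tropicalis* replicate 37 (up to 0.146), *CANX* without hybrid replicate 41 or 42 or *X. tropicalis* replicate 37 or 39 (up to 0.159), *BIRC3* without hybrid replicate 40 or 41 (up to 0.0868) and *WEE2* without hybrid replicate 42 (0.0697).

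In the ventral and BMP response list, 7 of 16 measured members were lower and 0 higher in the edgeR test, or 7 lower and 1 higher adjusted over the list alone, at an unadjusted p under 0.05 and with DESeq2 (camera adjusted p = 0.00137; adjusted p = 0.170 with an estimated correlation). The ligand gene *BMP7* fell from 788 CPM ± 92.9 to 300.3 CPM ± 77.6 (SD, n = 3; log2 fold change -1.39 ± 0.18 SE, adjusted p = 7.70e-04), the transcription factor gene *GATA2* by 1.38, *MSX1* by 2.73 and the Wnt ligand gene *WNT8A* by 1.07 on the log2 scale. In the organizer list, 4 of 17 members were lower and 0 higher in the edgeR test, also adjusted over the list alone (5 and 0 at an unadjusted p under 0.05, 4 and 0 with DESeq2; camera adjusted p = 0.0205; adjusted p = 0.668 with an estimated correlation). They were *IRX1* (-1.38), *PKDCC* (-0.996), *IRX3* (-1.35) and the Wnt antagonist gene *DKK1* (-1.15). The organizer list lost its call without hybrid replicate 42 (adjusted p = 0.0565) or *X. tropicalis* replicate 39 (adjusted p = 0.0574), and its lower members numbered 2 without either of these or hybrid replicate 41, where *IRX3* and *DKK1* lost their call (adjusted p up to 0.0757 and 0.0884). In the ventral and BMP response list 4 members were lower without hybrid replicate 40 (and 1 higher), hybrid replicate 41 or *X. tropicalis* replicate 39, and *GATA3* lost its call in all 6 fits (adjusted p up to 0.101), *ID3* in 5 (up to 0.158) and *BMP4* in those 3 (up to 0.0700); these 3 are named after their values were seen.

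In the ectoderm and neural plate list, 6 of 38 members were higher and 9 lower, or 6 and 13 adjusted over the list alone (camera adjusted p = 0.975). The lower members numbered 3 without hybrid replicate 41, 4 without *X. tropicalis* replicate 39 and 5 without *X. tropicalis* replicate 37 or 38. The neural factor gene *SOX2* fell from 320 CPM ± 70.3 to 76.9 CPM ± 26.5 (-2.06) and the keratin gene *KRT5* by 1.94. The epidermal factor gene *GRHL3* (1.53) and *ZNF750* (1.08) were higher, and so was *EPCAM* (7.88), whose counts came almost wholly from epcam.L. The rise of *ZNF750* lay mostly on *X. laevis* features, with znf750 at 192 CPM in hybrids and 169 CPM in *X. tropicalis*. In mesoderm, 6 of 26 members were higher and 3 lower, or 6 and 4 adjusted over the list alone (camera adjusted p = 0.975): *WNT11* (0.90), *FGF20* (1.92) and *FGF3* (2.68) rose and *HOXD1* fell. The rises lay mostly on *X. laevis* features (in hybrids fgf20.S at 17.1, fgf3.S at 12.2 and wnt11b.L at 163 CPM). The *X. tropicalis* features moved little, with fgf20 at 10.2 CPM in hybrids against 9.49 CPM in *X. tropicalis* and fgf3 at 2.52 against 2.26. For *WNT11*, wnt11b stood at 97.4 against 82.8 CPM and wnt11-like.1 at 80.9 against 99.0 CPM. In endoderm, 1 of 17 was higher and 4 lower, or 3 and 5 adjusted over the list alone (camera adjusted p = 0.288): *GATA6* (-1.83), *GATA4* (-1.04) and the ligand gene *NODAL* (-0.71) fell. The endoderm list passed as lower without hybrid replicate 40 (adjusted p = 0.0291), while its lower members numbered 0 without hybrid replicate 41 and 2 without hybrid replicate 42 or *X. tropicalis* replicate 39. *GATA6* and *GATA4* lost their call without hybrid replicate 41 (adjusted p of 0.0539 and 0.0548), and *NODAL*, summed over 25 features of a multigene family, without hybrid replicate 41 or 42 or *X. tropicalis* replicate 39 (up to 0.0808). The largest fall behind *NODAL* was in nodal3.2, a name of the organizer list (67.5 CPM in *X. tropicalis*, 24.4 CPM in hybrids). The feature nodal also fell (11.8 to 4.21 CPM), while nodal1 (11.1 to 9.87 CPM) and nodal2 (27.5 to 27.4 CPM) moved little.

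Over *X. tropicalis* features alone, the 5 lists of the last 2 paragraphs were lower in hybrids at the preset correlation. The median log2 fold change was -1.16 for organizer, -1.13 for ventral and BMP response and -1.12 for endoderm. It was -0.80 for mesoderm and -0.60 for ectoderm and neural plate. Hybrids carry a single *X. tropicalis* genome copy in place of a pair, which could lower these features and was not tested for the lists. The camera adjusted p was 7.93e-16 for ectoderm and neural plate (12 of 34 members lower), 7.86e-16 for organizer (9 of 17), 9.91e-15 for ventral and BMP response (9 of 16), 9.36e-12 for endoderm (8 of 14) and 1.22e-09 for mesoderm (7 of 21), with 0 members called higher by edgeR in any of them. With an estimated correlation only ventral and BMP response passed (adjusted p = 0.0204), and the adjusted p was 0.0680 for ectoderm and neural plate and for endoderm, 0.0682 for mesoderm and 0.0796 for organizer. At an unadjusted p under 0.05, 3 ectoderm members were higher and 0 in the other 4 lists, and DESeq2 called 1 ectoderm member higher. *GRHL3* stood at -0.40 and *EOMES* at -0.47 there without passing, and *SOX3* (-0.50) and *TFAP2A* (-1.05) were called lower, although all of these were higher over both species. This choice of features for the lists was made after seeing the data.

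The maternal and germ plasm list had 1 of 29 members higher, *WNT11*, and 1 lower, *TRIM36* (-0.66), or 4 and 2 adjusted over the list alone (camera adjusted p = 0.393). The rise of *WNT11* lay mostly on the *X. laevis* feature wnt11b.L. The list of cells of later differentiation had 3 of 22 members higher and 0 lower in the edgeR test, or 3 and 1 adjusted over the list alone (3 and 2 at an unadjusted p under 0.05 and with DESeq2; camera adjusted p = 0.288). The ciliary factor gene *FOXJ1* rose from 14.6 CPM ± 5.58 to 135 CPM ± 9.53 (3.21), with foxj1.L and foxj1.S at 59.0 and 60.3 CPM and the *X. tropicalis* feature at 13.7 CPM in hybrids and 14.1 CPM in *X. tropicalis*. *TTR* (7.13) and *HBG2* (438 counts against 3, ratio 171, 95% counting interval 58.1 to 833) were counted mostly on *X. laevis* features, *HBG2* on a single *X. laevis* feature alone. *TRIM36* lost its call without hybrid replicate 41 or 42 or *X. tropicalis* replicate 39 (adjusted p up to 0.0803), and *HBG2* without any hybrid replicate or *X. tropicalis* replicate 37 (up to 0.0994). Median, mean and test direction of a list differed in sign for glycolysis, fatty acid oxidation, apoptosis, centromere and kinetochore, mesoderm, endoderm, and ectoderm and neural plate.

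Among *X. tropicalis* features alone, 107 of 14079 were higher in hybrids and 422 lower, 77 and 320 of them by more than 2-fold. The focal adhesion gene nedd9, on chromosome 6, fell from 27.5 CPM ± 4.56 to 0.383 CPM ± 0.289 (SD, n = 3; log2 fold change -6.18 ± 0.54 SE, adjusted p = 1.52e-04). The sphingosine phosphate receptor gene s1pr5 fell by 6.16, kiaa1324l by 5.36, the prostaglandin receptor gene ptger4 by 4.84 and skida1 by 4.56 on the log2 scale. The feature cpa6 had no count in *X. tropicalis* and was at least 491-fold higher in hybrids. With 2 counts in *X. tropicalis*, gucy1a2 gave a ratio of 910 (95% counting interval 251 to 7521), and with 3 counts the innate immune adaptor gene card9 gave 370 (126 to 1799). The cell cycle inhibitor gene cdkn2b rose from 0.457 CPM ± 0.454 to 24.0 CPM ± 5.88 (5.72), and gadd45b-like from 1.36 CPM ± 0.774 to 51.1 CPM ± 4.33 (5.23). How many *X. laevis* reads lay on these higher features in hybrids was not measured. The rises may therefore not be of *X. tropicalis* transcripts alone. With library sizes from all features of both species, the median of the *X. tropicalis* features moved by -0.29, and 76 features were called higher and 1145 lower. DESeq2 called 398 higher and 795 lower, and without hybrid replicate 41 edgeR called 53 higher and 277 lower, without hybrid replicate 42 there were 60 higher, and without *X. tropicalis* replicate 39 there were 64 higher and 267 lower.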

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

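The alternatives over *X. tropicalis* features for the lists (at either correlation), over library totals for the lists, over names with features of both species and without each *X. tropicalis* library for the chromosomes were chosen after seeing the data. The contrast of 3L and 4L kept its direction, from -2.10 relative to orthologues to -0.98 without subtraction; its p was the floor of 0.0278 in each, so that p cannot show stability. For human-named genes, DESeq2 called 1046 higher and 686 lower, a test beyond 1.5-fold 383 and 101, and *X. tropicalis* features alone 90 and 350. For *X. tropicalis* features, DESeq2 called 398 and 795, no filter 244 higher, and library sizes over all features 1145 lower. The share of higher calls was 63.9% for human names against 68.96% with library totals, 79.1% beyond 1.5-fold and 20.5% over *X. tropicalis* features alone, and 20.2% for *X. tropicalis* features against 33.4% with DESeq2 and 6.22% with library sizes over all features. The stricter filter left 2997 *X. laevis* features above background, out of fewer tested. The difference in *X. laevis* share was 12.3 percentage points without the 100 largest features, and 8.09 without features of over 1% background, a selection that itself fixes the *X. tropicalis* share. Of the 21 lists, 5 were called, 0 with an estimated correlation, 9 over *X. tropicalis* features alone and 2 over these with an estimated correlation. With fry, which tests for a move 1 way without comparing with other genes, oxidative phosphorylation (adjusted p = 0.0711), ribosomal proteins (0.145) and organizer (0.105) did not pass, and the TCA cycle (0.0237), cholesterol (0.00642) and later differentiation (0.0171) lists did.

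Leaving out each library in turn gave 344 to 645 higher and 164 to 402 lower human names, 53 to 147 higher and 267 to 500 lower *X. tropicalis* features, 8219 to 9574 *X. laevis* features above background, a share difference of 10.7 to 11.8 points, a chromosome contrast of -1.94 to -1.79 and 3 to 7 called lists. The low ends for names and features came without hybrid replicate 41, except the 267, which came without *X. tropicalis* replicate 39. Of 111 named or called human names, 69 kept their call in each of these fits and 42 did not. Over *X. tropicalis* features alone the sign turned for *CTPS1* (-0.37), *MAT2A* (-0.20), *CCNE2* (-1.65), *EOMES* (-0.47), *SNAI2* (-0.0907), *GRHL3* (-0.40), *SOX3* (-0.50) and *TFAP2A* (-1.05), and the mesoderm list was lower (adjusted p = 1.22e-09; adjusted p = 0.0682 with an estimated correlation). That alternative leaves out the *X. laevis* counts, and the cause of the other moves was not tested. For *X. laevis* features the simulation recovered 1.04% of changes of 1 on the log2 scale. It shifted hybrids from a mean shared by both groups. The real contrast is against a low background, with a median log2 fold change of 5.87, so that share does not describe it.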

Other observations

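The tests on levels of orthologues, on S partners, on bins, on p53 members over *X. tropicalis* features, on reads assigned between species, on falls beyond 2-fold and on names still called lower were chosen after the results were seen, as were the genes named next. Further genes rose on the features of both species. The apelin receptor gene *APLNR* (log2 fold change 3.64, and 2.44 over *X. tropicalis* features), *RASL11B* (3.46 and 2.33), the signalling adaptor gene *TRAF4* (3.25 and 2.55), *SOCS4* (3.74 and 1.39) and the kinase gene *RIOK3* (2.102 and 1.28) passed the edgeR test in both counts. *ETS2* rose over both species (1.68) and stood at -0.00 over *X. tropicalis* features. Among falls, the creatine synthesis gene *GATM* (-1.94), the proton pump gene *ATP4A* (-2.01), the sodium pump subunit gene *ATP1B2* (-1.996), the uroplakin gene *UPK3B* (-2.07), the mucin gene *MUC5B* (-1.56) and the hexosamine pathway gene *GFPT1* (-1.32) passed over *X. tropicalis* features too. These counts are mostly the same data, so passing in both is no separate support. *UPK3B* has no *X. laevis* feature, so both counts of it rest on the same *X. tropicalis* feature and paternal transcripts could not be seen. *X. laevis* features held 0.552% of the hybrid level for *ATP4A*, 1.76% for *GATM* and 2.33% for *ATP1B2*. They held 18.8% for *MUC5B* and 23.8% for *GFPT1*.

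*X. laevis* chromosomes 3L and 4L were low in hybrids. The ratio to the *X. tropicalis* orthologues was lower by a log2 difference of -2.10 on 3L and 4L, while the orthologues differed by 0.08. Low total levels of the orthologues thus did not accompany the deficit. Orthologue counts may include RNA already in the *X. tropicalis* egg, which *X. laevis* counts from sperm-derived chromosomes do not. Low new transcription of the genes on 3L and 4L therefore stays open. Assignment of their reads to S copies would raise 3S and 4S, which lay at -0.39 against the other S chromosomes (exact permutation p = 0.139). The level of 3S and 4S without such reads is not known, so this comparison does not exclude it. Loss or silencing of stretches may account for the deficit: features above background clustered in bins of 100 in model order on 3L and on 4L (unadjusted permutation p = 1e-04 each, the smallest that 10000 orders can give), but 9 of the 16 other chromosomes were also under 0.05 (5 of them after adjustment), 3S with the same p, so the bins do not decide. That comparison with other chromosomes was added after the value on 3L was seen, and RNA counts cannot separate loss from silencing.

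The p53 and DNA damage list was higher in hybrids at the preset correlation (adjusted p = 0.0732 with an estimated correlation). Counts on *X. laevis* features were not the whole of the rise, since 7 of 10 higher members were called over *X. tropicalis* features alone. That does not exclude *X. laevis* transcripts as the source, because their reads may lie on *X. tropicalis* features. *GADD45B*, 1 of these 7, has no *X. laevis* feature. It was thus counted on the same feature both times, does not bear on the part of *X. laevis* features, and has no value among the shares given next. *X. laevis* reads assigned to *X. tropicalis* features could contribute and cannot be told apart here, since that share was not measured: it would have to be 73.3% for *MDM2*, 55.0% for *CCNG1*, 51.3% for *PLK2*, 27.1% for *CDKN1A*, 12.3% for *EDA2R* and 9.74% for *SESN1*, where the opposite share in *X. tropicalis* libraries was 1.003, 1.04, 1.89, 8.40, 25.4 and 2.98%. By more than 1 SD, 1 member needs over 50%, and the SD was added to this bound after a looser version, met by 3 members, had argued against the explanation. A later stage of the hybrid embryos also stays open, with a median of 0.0314 for the later differentiation list over *X. tropicalis* features (13 members, SD 1.14, wider than the bound written before the result, which would have excluded it).

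*X. tropicalis* features were called lower more often than higher. A single *X. tropicalis* genome copy in place of a pair would keep falls within 2-fold, and 23.9% of the 422 lower features (101) fell beyond 2-fold in a test against that threshold, which argues against it for these and leaves it open for the rest. Of the 352 human names of these features, 204 (58.0%, exact 95% interval 52.6 to 63.2%) were still called lower over both species and 13 higher. The names were picked by their fall in the same libraries, and the sum holds the same *X. tropicalis* counts. That share is therefore no independent test of whether added *X. laevis* copies made up the level. Of the 362 names called lower over both species, 25 have no *X. laevis* feature on which added copies could be seen. Whether added copies made up the level stays open: the median over all 352 was -0.74 (SD 0.904), below the bound written before the result by less than the SD, which was added after the value was seen. The hybrid genotype remains a possible explanation that no further test here addressed.

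*X. tropicalis* features of chromosomes 3 and 4, the partners of 3L and 4L, were not raised, with a difference of medians of 0.00663 (exact permutation p = 0.378). Human names placed on these chromosomes, summed over both species, differed by -0.0503 (exact permutation p = 0.0222). That comparison was not fixed beforehand. Its sums hold the counts of *X. laevis* features too, so it is no separate support for the deficit of 3L and 4L. The 10 splits of the 6 libraries are too few for a share under 0.05: the real split called 1003 human names, 529 *X. tropicalis* features and 9669 *X. laevis* features above background, the highest other split called 0 with edgeR in each case, and 1 of the 10 splits was as large, the real one.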
